A study of Mus musculus with 22 samples.

How the data were processed

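RNA was extracted, per the labels' protocols, from ulnae kept in RNAlater and milled in Trizol, and libraries were made from 4 ng of total RNA with a stranded total RNA kit. Per the submitters' processing notes the tools were STAR and RSEM and the genome build GRCm38; their versions and the annotation are not given in the sources used here. The deposited files hold expected counts per gene, 1 file per library, as whole numbers; the counts of near-identical genes such as Rn7s1 and Rn7s2 show that reads were apportioned between copies. They were used as estimated counts, rounded to whole numbers, which changed no value. Of 25471 genes 25428 were matched to a symbol by Ensembl identifier, and the lowest total of a listed gene over all libraries was 10. Coordinates and overlaps come from GENCODE M21 on the same build.

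Groups came from the labels: genotype (wildtype or CKO) and load (right limb loaded, left limb not), with the mouse number as the replicate. The main test was edgeR 4.0.16 (R 4.3.3) with limma 3.58.1: filterByExpr kept 18793 genes, TMM scaled the libraries, and glmQLFit with robust=TRUE and glmQLFTest were run in 1 model with a mean for each of the 4 groups over all 22 libraries (18 residual degrees of freedom, biological coefficient of variation 0.271). P-values were adjusted by Benjamini-Hochberg over the genes tested and called under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Contrasts were loaded against non-loaded in each genotype, their difference, and CKO against WT in each limb. A sixth contrast, the mean of both loading effects, was added after the data were seen and is reported only in the closing part. Log2 CPM values used a prior count of 2. No libraries were left out of the main fits, and no pair of libraries within a group was alike: the chi-square per gene lay between 30.1 and 601 over 54 pairs. Xist had 0 to 14 counts and Ddx3y 1111 to 2643, so that all mice appear male.

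32 gene lists, on bone cells, signalling, metabolism, stress, other cell types of a piece of bone and RNA quality, were fixed before the data were examined, as were the tests, most of the other settings and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, two-sided, adjusted over the lists of a contrast. Per mouse, the mean limb difference of a list was compared between genotypes by exact permutation over 330 splits and against 0 by exact sign flips. Named genes were the 10 highest and 10 lowest log2 fold changes past the threshold with at least 1 CPM, or, where fewer than 5 passed, which held for all 5 planned contrasts, the 5 with the smallest p and at least 1 CPM, unnamed gene models left out. Also named were up to 4 members of each list called by camera in its direction, and 13 genes fixed in advance. Some genes that the rule names are not reported here. Ltbp2 in loaded bone, the genes of the sixth contrast and the genes named as calls of other tools were chosen after their values were seen. Under other settings, p-values of single lists were computed only for lists called with the preset correlation, leaving out lists that make up the muscle and marrow scores where these were covariates; this restriction was set after the data were seen, and the number of lists called was computed for every such setting.

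The limbs of 1 number come from the same animal, so the numbers pair the samples. The limbs' deviations from their group means correlated at -0.256 to 0.415 (median 0.189) over the 11 mice, over 0.1 in 7, and the own limb correlated best in 6. Fits with the mouse as a block had 9 residual degrees of freedom. Further alternatives were median-ratio and upper-quartile scaling, other count filters, DESeq2 1.42.0, limma voom with quality weights or with the mouse as a random effect, muscle and marrow scores as covariates, thinning to the lowest total, and leaving out each mouse and each library. Other splits of the samples were refitted as the limits on time allowed, at most 100 per contrast.

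The fits were tested on simulated data with 200 changed genes among 18793, drawn from the fitted means and dispersions. Of 50 genes changed 2-fold, 74% were recovered for loading in WT, 56% for loading in CKO, 40% for the interaction, 74% for genotype in non-loaded and 66% in loaded bone. At 4-fold the shares were 92%, 96%, 94%, 98% and 96%, and at 1.5-fold 38%, 12%, 8%, 28% and 22%. The simulated genes varied independently, unlike those of tissue mixtures. The simulated fits called 126 to 157 genes in these contrasts, against 0 to 3 in the real data. Many true changes loosen the adjusted threshold, so with few changed genes the shares recovered would be lower. In the real non-loaded bones Ltbp2 differed between genotypes by 2.77 on the log2 scale and still missed the threshold (edgeR adjusted p = 0.516). Counts measure relative levels only; a different share of muscle or marrow RNA moves all genes of that tissue together.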

Results

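Total RNA was sequenced from the middle part of the ulna, a forearm bone, in 11 mice. Each mouse gave a right ulna that had been loaded mechanically and a left ulna that had not, so that 22 libraries fell into 4 groups. 7 mice were wildtype (WT) and 4 were conditional knockouts (CKO) of Tlr4, the receptor for bacterial lipopolysaccharide and for some products of damaged tissue; the series title places the receptor's role in osteoblasts, the cells that form bone. The labels used here give neither the loading regime nor the time of harvest. Libraries held 21999891 to 42833729 counts, and 18793 of the 25471 genes in the tables entered the tests. All values below are from the libraries as labelled.

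Tlr4 (ENSMUSG00000039005, chromosome 4, 66827584 to 66930284, GRCm38) was read first, as the targeted gene. Its level was 32.5 ± 4.89 CPM (counts scaled to library size, SD, n = 7) in WT non-loaded, 33.4 ± 4.82 in WT loaded, 30.1 ± 3.43 (n = 4) in CKO non-loaded and 29.2 ± 3.16 in CKO loaded ulnae. The mouse means of CKO and WT differed by -0.149 on the log2 scale, which was within chance (exact two-sided permutation test over 330 splits, p = 0.197). No edgeR contrast called Tlr4. Counts over the whole gene cannot show the loss of one exon or a loss in one cell type of the bone, so the genotype labels were not checked by these values. Ltbp2, which encodes a protein of extracellular microfibrils and was singled out after its values were seen, parted the genotypes more sharply. It lay between 26.5 and 73.5 CPM in 13 of the 14 WT libraries and between 205 and 344 CPM in 7 of the 8 CKO libraries. The exceptions were the library labelled WT loaded 686, at 380 CPM, and the library labelled CKO loaded 688, at 38.4 CPM.

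**Figure D1:**
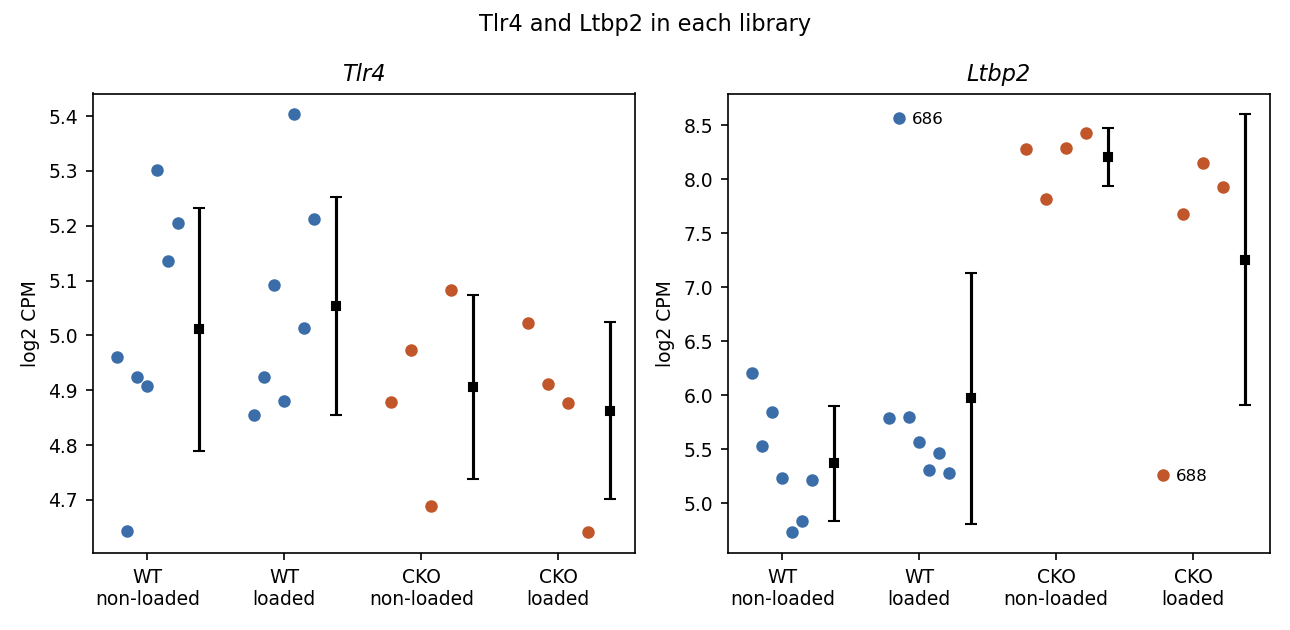
Level of Tlr4 (left) and Ltbp2 (right) in each of the 22 libraries, in log2 CPM; points are libraries, coloured by genotype, and black squares with bars are group means ± SD (n = 7 for WT and 4 for CKO). The loaded libraries of mice 686 and 688 stand at 8.57 and 5.26 log2 CPM of Ltbp2, each at the level of the other genotype.

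The bones carried different amounts of other tissue. Genes of the skeletal muscle list, such as the giant sarcomere protein gene Ttn, took 10.9 ± 3.15% of counts in WT non-loaded, 10.8 ± 2.81% in WT loaded, 10 ± 5.20% in CKO non-loaded and 13.8 ± 2.19% in CKO loaded libraries. The lowest share was 2.99% in CKO non-loaded 691 and the highest 16.9% in CKO loaded 698. Over the 22 libraries the muscle score ran against the score of red cell, neutrophil and B cell genes, with a correlation of -0.805. The limb difference of the muscle score was 0.82 ± 1.34 (mean log2 CPM of the list, SD, n = 4) in CKO and -0.03 ± 0.83 (n = 7) in WT mice; the CKO mean was 0.20 without mouse 691 and 1.24 without 688, and the WT mean ran from -0.22 without 699 to 0.18 without 694. A difference between genotypes in this limb difference did not pass an exact permutation test (n = 4 and 7, p = 0.227). In loaded ulnae alone the muscle score was higher in CKO by 0.619 (exact permutation p = 0.0182, adjusted p = 0.194 over 32 lists).

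**Figure D2:**
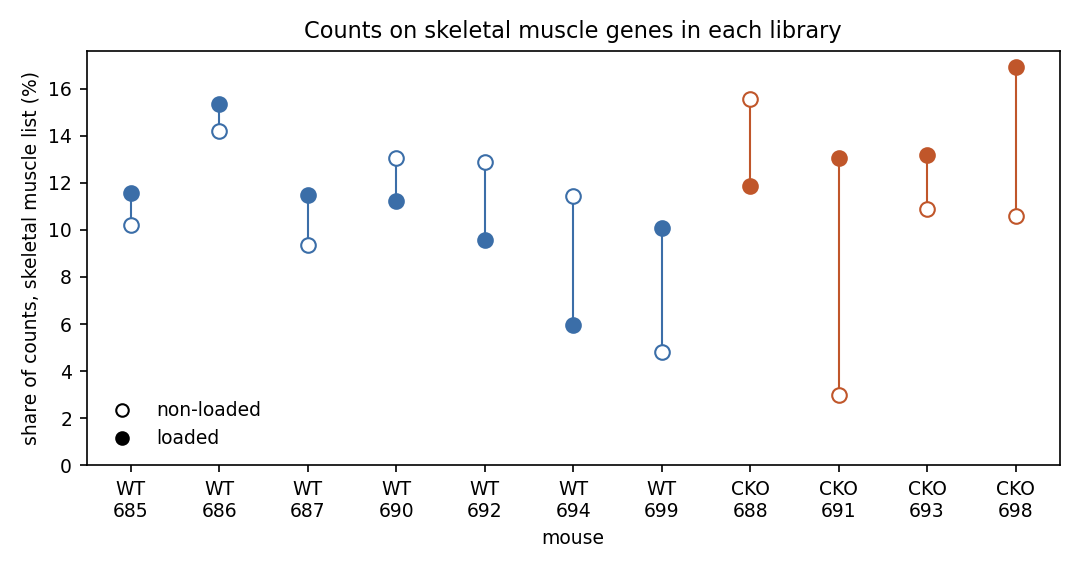
Share of each library's counts on the skeletal muscle list, in percent, for the 11 mice; open circles are non-loaded and filled circles loaded ulnae, joined within a mouse and coloured by genotype. The widest gap within a mouse is that of CKO mouse 691, from 2.99% to 13.1%.

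The first comparison asked what loading changes in wildtype bone. Wnt1, a secreted signal that drives bone formation, rose 5.02-fold, from 1.23 ± 0.797 to 6.21 ± 1.79 CPM, and was higher in the loaded ulna of 7 of 7 mice (log2 fold change 2.33 ± 0.34, SE; edgeR adjusted p = 0.0169). Wnt1 lies on chromosome 15, at 98789857 to 98793837. Genes of the immediate-early list, transcription factors and regulators switched on within minutes to hours of a stimulus, rose as a group. Of its 20 tested members, 18 lay above 0, with a median log2 fold change of 0.24. Camera called the list with its preset correlation (adjusted p = 6.85e-14) as well as with an estimated one (adjusted p = 0.00725). Fosb, Fosl1 and Egr1 passed the threshold adjusted over the list alone (adjusted p = 0.000868, 0.000868 and 0.00554), while 0 members passed over all genes. Per mouse, the list's mean response was 0.50 ± 0.21 and positive in 7 of 7 mice (exact sign-flip p = 0.0156, the smallest that 7 mice allow; adjusted p = 0.25 over 32 lists).

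Among the genes next to Wnt1 by p-value, these missed the threshold in WT: the metallothionein gene Mt2, with 1.69 ± 0.31 and adjusted p = 0.114; Ptgs2, which encodes the prostaglandin synthase COX-2, with 1.73 ± 0.33 and 0.143; and Fosb, with 1.36 ± 0.27 and 0.15. Each was higher in the loaded limb of 7 of 7 mice. Dmp1, a matrix protein gene of osteocytes, gave 0.75 ± 0.20 (adjusted p = 1) and was higher in 7 of 7 mice, and the ligand gene Wnt7b gave 1.43 ± 0.47 (adjusted p = 1). Sost, the osteocyte gene for the Wnt inhibitor sclerostin, gave -0.45 ± 0.21 (adjusted p = 1) and was higher in 2 of 7 mice. Bglap gave -0.60 ± 0.56, Col1a1 -0.55 ± 0.50, Postn -0.26 ± 0.34, Timp1 0.58 ± 0.32 and Il1b -0.10 ± 0.41, all at adjusted p = 1. Il6 had 1 to 17 counts per library and was not tested.

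Camera with its preset correlation called 10 of the 32 lists in WT, 8 higher and 2 lower; for the other 9 the adjusted p with an estimated correlation was 0.437 or more. Among them, all 21 members of the osteoblast matrix list lay below 0 with a median of -0.30, 0 of them past the threshold adjusted over the list alone or over all genes (adjusted p = 1e-05 with the preset, 0.903 with an estimated correlation). Of other called lists, 28 of 28 cell cycle (median 0.21), 15 of 15 erythroid (median 0.37) and 11 of 11 megakaryocyte members lay above 0 and 77 of 82 ribosomal protein genes below. Each stood at 0.903 with an estimated correlation, 0 of their members passed, and per mouse the means of the first 3 were below 0 in 686 and 699. The erythroid and megakaryocyte calls were lost without mouse 685 (adjusted p = 0.0577 and 0.926) or 694 (0.0984 and 0.146), and the ribosomal protein call without 699 (0.723). The osteoblast matrix members with the smallest p were Bmp3, with -0.51 ± 0.23, and Pth1r, the parathyroid hormone receptor gene, with -0.39 ± 0.22, both at adjusted p = 1. The inflammatory target list (adjusted p = 2.1e-05, and 0.437 with an estimated correlation) had 14 of 21 members above 0, and 3 members passed adjusted over the list alone; Ptgs2 and the chemokine gene Ccl2, with 1.64 ± 0.47, had its smallest p. Per mouse the inflammatory targets were higher in 7 of 7 WT mice, by 0.40 ± 0.25 (exact p = 0.0156, adjusted p = 0.25). With the median over the list in place of the mean they were higher in 6 of 7, by 0.19 ± 0.35 (exact sign-flip p = 0.188). In edgeR 1 gene was called in WT. Of 18793 genes 439 had an unadjusted p under 0.05, where 939.6 are expected by chance in each contrast. With the mouse as a block the call rose to 2 genes, with Wnt1 (adjusted p = 0.0445) among them. The Wnt1 call was lost without mouse 685, 690 or 692 (adjusted p = 0.168, 0.253 and 0.0996). It was also lost without the non-loaded library of any of these, the loaded library of 690, or mice 691 and 699 together (0.119). The same held with only the WT groups in the fit (0.0767), and with the block without mice 691 and 699 (0.181) or 686 and 688 (0.0772). DESeq2 and limma voom with quality weights or with the mouse as a random effect called Wnt1 (adjusted p = 5.59e-08, 0.00313 and 0.00189). Its log2 fold change lay between 2.13 and 2.75 in all settings tried.

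**Figure D3:**
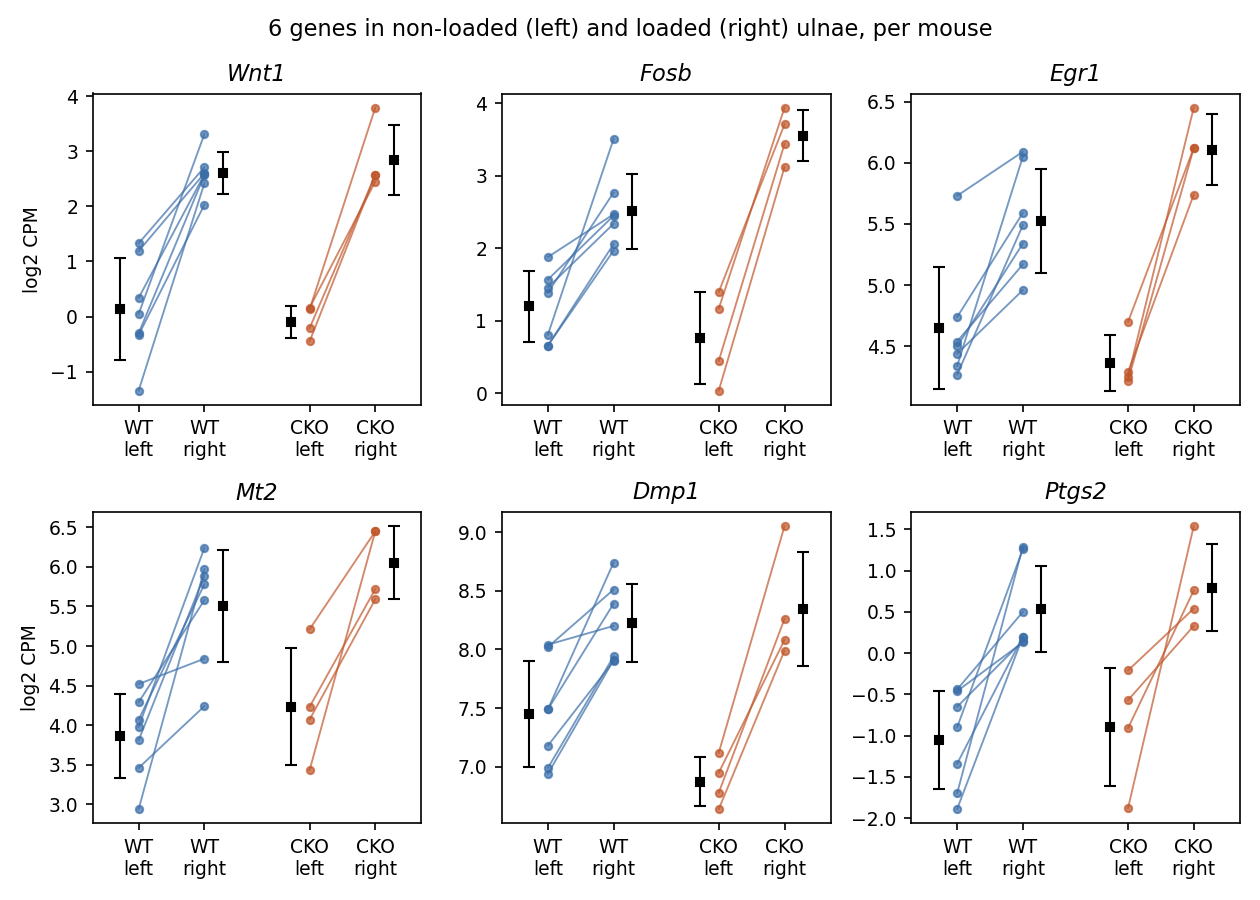
Level of 6 genes, in log2 CPM, in the non-loaded (left) and loaded (right) ulna of each mouse; lines join the limbs of 1 mouse, colours mark genotype, and black squares with bars are group means ± SD (n = 7 WT, 4 CKO). Wnt1 rises in each of the 11 mice, by 2.33 in WT and 3.13 in CKO on the log2 scale of the edgeR fit.

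The second comparison put the same question to the CKO mice. Fosb, which encodes a subunit of the AP-1 transcription factor, rose from 1.75 ± 0.749 to 11.9 ± 2.86 CPM (log2 fold change 2.77 ± 0.37, edgeR adjusted p = 0.00388). Wnt1 rose 8.73-fold from 0.887 ± 0.185 to 7.73 ± 4.04 CPM (3.13 ± 0.47, adjusted p = 0.0118). Egr1, another immediate-early transcription factor gene, rose from 20.7 ± 3.49 to 70.0 ± 13.8 CPM (1.76 ± 0.29, adjusted p = 0.0366). Each was higher in the loaded limb of 4 of 4 mice. With muscle and marrow covariates Fosb alone was called, and Wnt1 (3.14) and Egr1 (1.85) missed the threshold, both at adjusted p = 0.0697. With the mouse as a block and both covariates Fosb, Dmp1 and Arc were called, but not Wnt1 (adjusted p = 0.0514) or Egr1 (0.101). The calls of Fosb, Wnt1 and Egr1 were all lost with only the CKO groups in the fit (adjusted p = 0.101, 0.101 and 0.0838) and without mice 686 and 688 (0.137, 0.137 and 0.282). Those of Fosb and Wnt1 were lost without mice 691 and 699 (0.0848 each). Fosb lies on chromosome 7, at 19302696 to 19310051, and Egr1 on chromosome 18, at 34859823 to 34864984. Dmp1 was 2.88-fold higher (log2 fold change 1.53 ± 0.27, 4 of 4 mice) and missed the threshold at adjusted p = 0.071, but was called with the mouse as a block (adjusted p = 0.0181). Rrad, a small GTPase gene, also missed it (3.35 ± 0.63, adjusted p = 0.0997).

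Of the 20 immediate-early genes 18 lay above 0 in CKO, with a median of 0.56, and the list was called with the preset (adjusted p = 1.46e-18) and with an estimated correlation (adjusted p = 0.00137). Fosb, Egr1, Egr3, Egr2 and Fos passed adjusted over the list alone, and Fosb and Egr1 over all genes. Egr3 gave 1.13 ± 0.26 and Egr2 0.98 ± 0.29, at adjusted p = 0.294 and 0.739 over all genes. Per mouse the list's response was 0.84 ± 0.33 and positive in 4 of 4 mice, a number of mice too small for an exact sign-flip p under 0.05. Ptgs2 gave 1.75 ± 0.43 (adjusted p = 0.494) and was higher in 4 of 4 mice. Wnt7b gave 1.38 ± 0.62 (adjusted p = 0.739), Sost 0.32 ± 0.28 (adjusted p = 0.739), Bglap 0.36 ± 0.74 (adjusted p = 0.868) and Col1a1 0.04 ± 0.67 (adjusted p = 0.987). Postn, Timp1 and Il1b gave 0.15 ± 0.45, 0.38 ± 0.43 and -0.42 ± 0.54, none past the threshold.

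Camera with the preset called 24 lists in CKO, 13 higher and 11 lower, and for the other 23 the adjusted p with an estimated correlation was 0.445 or more. The higher side held the skeletal muscle list (20 of 20 members above 0, median 0.55) with oxidative phosphorylation (28 of 28, median 0.37) and fatty acid oxidation. The lower side held the T and NK cell list (15 of 15 below 0, median -0.72), the B cell and neutrophil lists and the cell cycle list (28 of 28 below 0, median -0.52). With muscle and marrow covariates the cell cycle list turned and was called higher (adjusted p = 0.000358), and oxidative phosphorylation (0.971) and fatty acid oxidation (0.0575) missed the threshold. Without mouse 691 the cell cycle (0.572) and neutrophil (0.136) lists missed it. In these lists 0 members passed over all genes or over their list alone. The muscle share was 13.8% in CKO loaded and 10 ± 5.20% in CKO non-loaded libraries. In edgeR 3 genes were called and 677 had an unadjusted p under 0.05; with the mouse as a block 5 were called, with Dmp1 among those added. Without mouse 688 or without mouse 691 the count fell to 0, and without mouse 693 or 698, or without the non-loaded library of any of the 4 mice, it was 1, Fosb.

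The third comparison, the interaction, asked whether the response to loading differed between genotypes. No gene passed in edgeR (lowest adjusted p = 0.697; 488 genes at an unadjusted p under 0.05), and DESeq2 and limma voom with quality weights also called 0. The response of Wnt1 was larger in CKO by 0.80 ± 0.56, of Dmp1 by 0.78 ± 0.34, of Sost by 0.77 ± 0.35 and of Ptgs2 by 0.02 ± 0.60 on the log2 scale, all at adjusted p = 0.697 or more. The genes with the smallest p were Gata3, a transcription factor gene of T cells (-0.996 ± 0.248), the immunoglobulin genes Igkv9-120 (-3.24 ± 0.87) and Igkv16-104 (-3.44 ± 0.95), the inflammasome gene Nlrc4 (-1.01 ± 0.28) and the interferon-induced Mx2 (-1.04 ± 0.29), all of which missed the threshold at adjusted p = 0.697. Immunoglobulin V genes have near copies that share reads, so single members are uncertain.

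For the immediate-early list the difference of the mouse responses was 0.34, CKO above WT (exact permutation p = 0.0727, adjusted p = 0.491), and for the inflammatory targets -0.32 (exact p = 0.167, adjusted p = 0.491); of the 32 lists the T and NK cell list had the lowest exact p, 0.0424 (adjusted p = 0.491). Camera with the preset called 25 lists in the interaction, 13 higher and 12 lower, and with an estimated correlation 0, with adjusted p from 0.528 to 0.709 for those 25. With the mouse as a block the preset called 23. With muscle and marrow covariates it called fewer, and some of the 25 turned direction. The counts of called genes come from 7 and 4 mice. In 35 fits with 4 WT mice each beside the 4 CKO mice, edgeR called a median of 0 genes in WT (0 to 1) and 2 in CKO (0 to 8), with more in CKO in 34 fits and as many in 1. All hold the same 4 CKO mice and overlapping sets of WT mice, so they are not 35 independent tests. With all mice the order of the counts turned with covariates (WT 5, CKO 1), with block and covariates (19 and 3) and in limma voom with quality weights (34 and 18). Across the 18793 genes, which are not independent replicates, the fold changes of the 2 genotypes had a Pearson correlation of -0.105 and a Spearman correlation of -0.271. The sign of the Pearson correlation depends on single mice: it was -0.31 without mouse 699, but 0.164 without 694, 0.122 without 691 and 0.004 without 692. Of 17 genes with an unadjusted p under 0.001 in WT, 17 had the same sign in CKO. Between 4 and 3 WT mice the correlation had a median of 0.045 over 35 splits (-0.327 to 0.199), from WT to CKO of -0.069 (-0.392 to 0.358).

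The fourth comparison set the genotypes side by side in non-loaded bone. Ltbp2 (chromosome 12, 84783212 to 84876532) was 2.77 ± 0.57 higher in CKO on the log2 scale and missed the threshold with all libraries in the fit (edgeR adjusted p = 0.516); it was called without mouse 686 and, at 2.76 and adjusted p = 0.000156, without mice 686 and 688. The 4 other genes with the smallest p-values were immunoglobulin genes with near copies, and they missed the threshold too: Igkv9-120, with 3.07 ± 0.57 and adjusted p = 0.284, Igkv3-4, with 2.79 ± 0.60 and 0.619, Ighv2-9, with 2.88 ± 0.65 and 0.837, and Igkv4-61, with 3.57 ± 0.86 and 0.976. Sost gave -0.70 ± 0.25, Dmp1 -0.63 ± 0.24, Bglap -1.10 ± 0.68 and Col1a1 -0.82 ± 0.61, each at adjusted p = 0.976, and Wnt1 gave -0.48 ± 0.42 at the same adjusted p.

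No gene was called in non-loaded bone by edgeR, with 572 at an unadjusted p under 0.05; DESeq2 called 2, Ltbp2 and Igkv9-120, and limma voom with quality weights 2, Ltbp2 and Gm42639. Camera with the preset called 18 lists, among them osteoblast matrix (20 of 21 members below 0 in CKO, median -0.48, adjusted p = 4.97e-08) and osteocyte genes (13 of 14 below 0, median -0.59, adjusted p = 4.97e-08), each at 0.71 with an estimated correlation and with 0 members of either past the threshold adjusted over the list alone or over all genes. The cell cycle list (28 of 28 above 0, median 0.43, adjusted p = 3.96e-08) and the erythroid, B cell, T and NK cell and ribosomal protein lists were called higher in CKO, each also at 0.71 with an estimated correlation. With muscle and marrow covariates the cell cycle (0.698) and ribosomal protein (0.227) calls were lost. Without mouse 691 those of all 5 but the B cell list were lost (0.139 to 0.682), and that of the T and NK cell list also without 688 (0.055) or 694 (0.0929). With an estimated correlation 0 lists were called, and the adjusted p of those 18 ran from 0.71 to 0.784. The library CKO non-loaded 691, with the lowest muscle share of 2.99%, is 1 of the 4 CKO libraries here, and without that mouse the preset called 9 lists, 3 of them among the 18.

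The last comparison set the genotypes side by side in loaded bone. Here too Ltbp2 was higher in CKO, by 1.03 ± 0.56, which missed the threshold with all libraries (adjusted p = 0.601) and was called without mice 686 and 688, at 2.40 and adjusted p = 0.00115, as the one gene of that fit. The genes with the smallest p missed the threshold at adjusted p = 0.601: Rrad (1.83 ± 0.49), Uchl3, a ubiquitin hydrolase gene (0.48 ± 0.13), the leukocyte transcript Mir142hg (-0.93 ± 0.26), Nlrc4 (-0.72 ± 0.21) and Banp (-0.41 ± 0.12). Wnt1 gave 0.32 ± 0.36, Dmp1 0.15 ± 0.24, Sost 0.07 ± 0.25 and Ptgs2 0.26 ± 0.36 (adjusted p = 0.733, 0.795, 0.914 and 0.766).

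No gene was called in loaded bone by edgeR with all libraries, with 1280 at an unadjusted p under 0.05, and DESeq2 and limma voom with quality weights called 0 as well. Camera with the preset called 16 lists, 7 higher and 9 lower in CKO, and 0 with an estimated correlation, with adjusted p from 0.64 to 0.866 for those 16. The higher side held oxidative phosphorylation (28 of 28 members above 0, median 0.48), fatty acid oxidation (23 of 24, median 0.39), skeletal muscle (20 of 20, median 0.64) and mitochondrial RNA (14 of 14, median 0.63), the last of which was not called with covariates (0.0639). The lower side held, among others, the osteoclast list (18 of 18 below 0, median -0.47) and the T and NK cell list (15 of 15 below 0, median -0.50). The muscle share was 13.8% in CKO against 10.8% in WT loaded libraries, and without mouse 698, whose loaded library held 16.9%, the preset called 9 lists.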

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

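The tests of the exchange of libraries were chosen only after the Ltbp2 values were seen. In each group of 4 or 7 libraries, the gap of the highest or lowest library to its neighbour was divided by the group's range. Of 216 such tests 28 passed Dixon's 95% critical value, in 10 libraries, where chance gives about 1 in 20, and the measures are related to each other.

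Most of these values belong to the 2 non-loaded libraries with the lowest muscle shares. WT non-loaded 699 was highest in globin share (0.07225%, next 0.03003%) and in the scores (mean log2 CPM) of Tlr4 and NF-kB signalling (4.835), interferon response (3.42) and cell cycle (6.414). It was lowest in the Wnt pathway (1.858), TGF-beta, BMP and YAP (4.095) and adipocyte (1.702) scores. Its log2 CPM of Wnt7b (-2.06) was lowest in the group, and those of Il1b (4.93) and Egr1 (5.73) highest. CKO non-loaded 691 was lowest in the skeletal muscle (8.834, next 11.24), neurotrophin (1.506), extracellular matrix (5.492), TGF-beta, BMP and YAP (4.159), ion channel (4.31) and tendon and periosteal fibroblast (2.516) scores and in Postn (6.07 log2 CPM), and highest in the share of 45S ribosomal RNA models (5.128%).

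Of the other libraries, WT loaded 694 had the highest globin share (0.09098%) and CKO loaded 688 the highest share of 45S models (6.097%, next 2.729%). CKO loaded 698 was lowest in the Tlr4 and NF-kB signalling (4.318) and monocyte and macrophage (3.95) scores. CKO non-loaded 698 was highest in the heat shock score (5.56) and WT non-loaded 685 in the marrow stroma score (5.902). Wnt1 stood at 3.79 log2 CPM in CKO loaded 693 (next 2.57), and Egr1 at 4.7 in CKO non-loaded 693. Ltbp2 stood at 8.57 log2 CPM in the library labelled WT loaded 686, and at 5.26 in the library labelled CKO loaded 688.

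An exchange of the loaded libraries of mice 686 and 688 is a candidate explanation for the Ltbp2 values: over immunoglobulin V genes, whose use differs from mouse to mouse, crossing them raised the summed correlations between limbs by 0.466, the one rise among 55 pairs of mice (next -0.025). Of 6 versions of this test all gave a rise, but only those on immunoglobulin V genes, with and without covariates, ranked this pair first; over genes with a mean log2 CPM over 1 it ranked 8 (gain 0.165), and over the 300 most variable genes 7 (0.287), each 2 with covariates. Beside Ltbp2, 3 genes, chosen after their values were seen, parted the other 13 WT and 7 CKO libraries by narrower gaps, and loaded 686 and 688 stood at 3.97 and 4.23 log2 CPM for Banp (WT 4.08 to 4.55, CKO 3.68 to 4.02), at 0.89 and -1.32 for D030025P21Rik (-2.42 to -0.58, -0.42 to 0.42) and at 5.11 and 5.13 for Vgll4 (5.16 to 5.51, 4.9 to 5.11). Own-limb correlations over immunoglobulin V genes were 0.036 for 686 and -0.063 for 688 (mean -0.014, lowest of the other 9 mice 0.111). With covariates they were 0.007 and -0.055 (lowest other 0.055). Both lying below all others had been set, after Ltbp2 was seen, to count against correct labels. A demand that this hold in all 6 versions was added after these values were seen. Over genes with a mean log2 CPM over 1 they were 0.509 and -0.014 (others -0.579 to 0.447). With covariates these were 0.117 and 0.299 (others 0.193 to 0.613). Over the 300 most variable they were 0.168 and 0.083 (others -0.267 to 0.537), and with covariates 0.074 and 0.128 (others -0.022 to 0.486). Own limbs matched best in 8 of 11 mice over immunoglobulin V genes, but in 1 to 3 over the other sets, which therefore decide little. The immunoglobulin V genes argue against correct labels but do not exclude them. The labels were kept as given, no fit with exchanged labels was made, and a genotype that the labels record wrongly for 1 limb only was not tested.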

How the results depend on the processing

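Leaving out mice 691 and 699, leaving out mice 686 and 688, the average over genotypes, and the block with covariates for lists and for the correlation of fold changes were chosen after the data were seen. Counts of genes and lists are in the order WT, CKO, interaction, non-loaded, loaded and average, and only counts that moved by over 1.5 times and lists that turned are given. Other scalings, filters, thinning and robust fitting moved none, and the interaction stayed at 0 in every setting run. Genes called: with the mouse as replicate block WT 2, CKO 5 and average 11 (from 1, 3 and 17); with muscle and marrow covariates WT 5 and CKO 1; with block and covariates WT 19 and average 54. With DESeq2 WT 11, CKO 22, non-loaded 2 and average 33. With limma voom and quality weights 34, 18, 2 and 89. With only the groups compared CKO had 0 and non-loaded 1. Without mice 691 and 699 WT had 0 and CKO 1, and with the block 0, 0 and average 5. Without mice 686 and 688 CKO had 0, non-loaded 1 and loaded 1, and with the block WT 0, CKO 0 and average 6. Without each mouse or library WT had 0 to 2, CKO 0 to 4, non-loaded 0 to 1 and average 10 to 24.

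Lists called fell with an estimated correlation to 1, 1, 0, 0, 0 and 1 (from 10, 24, 25, 18, 16 and 22), and by fry to 1, 1, 0, 0, 0 and 1. With covariates CKO had 14, the interaction 11, non-loaded 11 and the average 13, and with block and covariates CKO 12, interaction 11 and average 14; without mice 691 and 699 the average had 12, or 13 with the block. Without each mouse CKO had 14 to 24, the interaction 15 to 25, non-loaded 9 to 21, loaded 9 to 21 and the average 12 to 28. With covariates these lists turned direction (adjusted p): in CKO Tlr4 and NF-kB signalling 0.919, extracellular matrix 0.971, cell cycle 0.000358, megakaryocyte 0.477, tendon 0.566, Schwann cell 0.254 and mitochondrial RNA 0.364. In the interaction they were neurotrophin 0.654, extracellular matrix 0.419, cell cycle 0.419, megakaryocyte 0.682, Schwann cell 0.454, mitochondrial RNA 0.989 and ribosomal protein 0.0142. The others were megakaryocyte 0.0211 in non-loaded and cell cycle 0.154 in loaded bone. Without mouse 691 lists turned as well, some of them the same. Over all mice left out their adjusted p ran in CKO from 0.00199 to 0.848 for tendon and 0.000626 to 0.533 for Schwann cell, and in the interaction from 0.00227 to 0.819 for Schwann cell. In non-loaded bone it ran from 0.0069 to 0.787 for neurotrophin, 0.0102 to 0.43 for Tlr4 and NF-kB signalling, 5.82e-07 to 0.45 for interferon, 9.9e-07 to 0.375 for neutrophil, 0.000601 to 0.423 for megakaryocyte and 0.00143 to 0.502 for tendon. The cause was not tested.

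With the block, preset list calls changed in WT for osteoclast (adjusted p = 0.0462) and neutrophil (0.0462), in the interaction for neurotrophin (0.0574), TGF-beta, BMP and YAP (0.0506), Schwann cell (0.068) and marrow stroma (0.0491), and in the average for osteocyte (0.0413); the counts of genes it changed are given above. The correlation of fold changes ran from -0.31 to 0.164 without each mouse and was 0.128 with block and covariates. All mice appear male, so sex as a covariate was not run. At the depths given, Il6, with 1 to 17 counts per library, could not be tested.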

Other observations

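The contrast that averages loading over both genotypes, the tests of Tlr4 against marrow scores and of its exons, those without mice 686 and 688 and the splits for lists with an estimated correlation were chosen only after the results were seen.

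Averaged over both genotypes, edgeR called 17 genes, all higher in loaded bone. Beside Wnt1 (log2 fold change 2.73 ± 0.29, adjusted p = 9.03e-05) and Fosb (2.06 ± 0.23, 9.03e-05) they held Ptgs2 (1.74 ± 0.27, 0.00531), the metallothionein genes Mt2 and Mt1, Dmp1 (1.14 ± 0.17, 0.0034) and Egr1 (1.30 ± 0.18, 0.00176). Secreted signals were among them, with the hedgehog ligand gene Ihh (1.19 ± 0.20, 0.00747) and Bmp2 (0.64 ± 0.12, 0.0223), and so were Has1, which encodes a hyaluronan synthase, the small GTPase genes Rrad and Gem, Arc, Gprc5a and Phlda1. Has1, Phlda1, Bmp2, Mt1 and Gprc5a were higher in 10 of 11 mice and the other 12 in 11 of 11. With the mouse as a block 11 genes were called, and Ptgs2, Rrad, Mt1, Has1, Gprc5a, Bmp2 and Phlda1 were no longer among them (adjusted p from 0.0517 for Mt1 up), while Ccl2 was added (adjusted p = 0.0313). Without mouse 693 the count was 10.

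All 20 immediate-early genes lay above 0 in this average (median 0.35), 10 of them past the threshold adjusted over the list alone and 2 over all genes. The list was called with an estimated correlation as well (adjusted p = 3.12e-05). However, 6 of 100 splits within mice, the real one among them, called as many lists that way. Camera with the preset called 22 lists, for the other 21 of which the adjusted p with an estimated correlation was 0.304 or more.

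Other splits of the same libraries were refitted. Numbers of splits with as many genes or lists count the real one. Shares were not adjusted for the number of split tests. For genes called, the share was under 0.05 for loading in WT (1 gene, 3 of 100 splits, highest other 1). Within WT mice it was 1 of 64 (highest other 0). This call was lost without mouse 685, 690 or 692, although leaving out a mouse also weakens the test and the log2 fold change stayed at 2.13 or more. As it is 1 gene and the shares were not adjusted, chance is not excluded by it. The share was also under 0.05 on average (17 genes, 1 of 100). The highest other there was 14, from the split that exchanged the limbs of mouse 694 alone. In CKO the share was under 0.05 only with splits that ignore the pairing (3 genes, 1 of 35, highest other 0). The 8 splits within CKO mice are too few for a share under 0.05 (3 genes, 1 split, highest other 0; 24 lists, 2 splits, highest other 25). For the interaction and both genotype contrasts the real count was 0 genes, which every split reaches (100 of 100), so these counts test nothing; the highest others were 0, 4023 for non-loaded and 1 for loaded bone. The 5 other splits that called any gene in non-loaded bone each put CKO 691 and WT 699 in the group of 4, which points to a structure of the samples, though 7 other splits with both in that group called 0 genes. For lists called with the preset, chance could not be excluded in any contrast. They were 10 in WT (94 of 100 splits, highest other 23; within mice 56 of 64, highest 26) and 24 in CKO (4 of 35, 25). The interaction had 25 (7 of 100, 29), non-loaded bone 18 (51 of 100, 23), loaded 16 (43 of 100, 24) and the average 22 (19 of 100, 28). With an estimated correlation 1 list was called in WT, at a share under 0.05 (3 of 100 splits, highest other 1). Within WT mice the share was 3 of 64 (highest 1). This test was chosen after the results were seen and its shares were not adjusted, so chance is not excluded. The per-mouse sign-flip test of the same list had adjusted p = 0.25. Its exact p of 0.0156 is the smallest that 7 mice allow, so this miss does not count against the list. In CKO, with 1 list, the share was under 0.05 only with splits that ignore the pairing (1 of 35, highest other 0). The 8 within mice are too few (1 split, highest 0). For the 1 list of the average the share was over 0.05 (6 of 100, highest 1). The 5 other splits left the limbs of most mice as labelled, or exchanged those of most mice together. They therefore held much of the real difference. The 0 lists of the other 3 contrasts test nothing (100 of 100, highest others 0, 0 and 2).

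Fold changes of loading in WT and in CKO correlated at -0.105 across genes, a value whose sign turned without mouse 691 (0.122), 692 (0.004) or 694 (0.164) and which was -0.31 without 699. Unequal amounts of muscle and marrow RNA in the limbs may account for this. The first component of the 11 limb differences, computed over 13700 genes outside those lists and holding 66% of their variance, followed the muscle score with r = 0.961 (permutation p = 1e-05, the smallest possible; rho = 0.918, p = 0.00019; r = 0.904 without mice 691 and 694; 2 relations tested, adjusted p = 2e-05 and 0.00038). Only the listed genes were left out, so other genes of these tissues stayed among the 13700. That the component follows the muscle score was therefore likely in advance, and it does not show what lowered the correlation. With the mouse as a block and both scores as covariates the correlation across genes was 0.128. Without mice 686 and 688 the correlation stayed below 0 (-0.22). As leaving out single mice turned its sign, this value does not decide whether an exchange of these mice contributed. A response that differs with genotype stays open. Splits of the mice were compared by mean limb differences in log2 CPM, not by edgeR fold changes, and the real correlation was then -0.124. Of 330 splits 85 gave a correlation as low (lowest -0.549). A share of 0.05 or more had been set beforehand to count against it, but with 4 CKO mice such a share does not exclude a difference.

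Tlr4 counts were not called lower in CKO libraries. RNA of marrow cells outside the deleted lineage may hold the level up. Over the 11 mice Tlr4 followed the mean neutrophil and monocyte score with r = 0.733 (permutation p = 0.00989, adjusted p = 0.00989). By rank, rho was 0.682 (permutation p = 0.025, adjusted p = 0.025), and r was 0.831 without mice 699 and 691. Such a relation can arise with or without a deletion in another lineage, so it does not show why Tlr4 was not lower in CKO. A deleted exon cannot be told apart from no deletion, since counts over the whole gene (CKO minus WT -0.149) do not resolve exons. An exchange of mice 686 and 688 as the sole reason for the Tlr4 level is argued against by the difference without them, -0.212 (exact permutation p = 0.107, 84 splits). A loss of over 0.5 had been set as its mark. These values do not bear on whether the libraries were exchanged. Which cells the deletion reached was not given in the sources used here.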
